A study of Danio rerio with 6 samples.

How the data were processed

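RNA sequencing was done on pools of hearts dissected from zebrafish embryos at 56 hours post fertilisation, raised at 28 degrees Celsius. The study had 3 groups of 2 pools each: pitx2c mutant hearts (mutant), hearts carrying a transgene in which the heart muscle promoter myl7 drives pitx2c and a nuclear green fluorescent protein (OE), and wild-type hearts (WT). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was isolated with a micro kit and DNase treatment, and 5 ng of total RNA entered a stranded, low-input total RNA library kit. Such a kit captures RNA with and without a poly(A) tail, so ribosomal RNA takes part of the reads. The labels name the libraries as pools but do not say whether embryos came from separate clutches. The limma p-values thus measure only the spread between these pools, part of which can be technical.

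The values were deposited by the authors as whole-number normalised read counts, treated here as a score rather than as counts, for 22941 genes in the 6 libraries. STAR 2.4.0a and featureCounts 1.4.5-p1 of the Subread package are named in the submitters' processing notes, with the zebrafish build GRCz10 (danRer10). The normalisation method and the strand setting of the counting are not given in the sources used here. That the values were scaled after counting was read from the values: all libraries had the same median ratio to the geometric mean, between 1.0082 and 1.0121, and some whole numbers were missing or doubled at regular steps, as rounding after multiplication by 1 factor per library gives. Whole reads could not be recovered gene by gene, so the count tests planned for raw counts were not used. Because the strand setting is unknown, overlapping genes on opposite strands cannot be separated, and families of near-identical genes (globins, fast myosins, ventricular myosins) can share reads.

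The deposited values summed to between 7370143 and 8934484 per library. Read totals estimated from the rounding steps were 6900000 and 8890000 for mutant 1 and 2, 8170000 and 7150000 for OE 1 and 2, and 10200000 and 7940000 for WT 1 and 2. The estimate for OE 2 is the least certain, since its steps matched the predicted ones with a correlation of 0.356. Mitochondrial ribosomal RNA took 17.0 to 22.2% of the values and the single gene zgc:158463 took 8.16 to 14.0%, so the depth for other genes is lower than these totals. The number of genes listed at 0 ranged from 364 to 1508 per library.

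Genes with a value of at least 10 in at least 2 of the 6 libraries were tested, which left 18352. Values were transformed as log2(value + 1), so fold changes are on that scale and understate the change of low genes. All 6 libraries entered 1 linear model with limma 3.58.1 in R 4.3.3, with a mean-variance trend and group as the only term, on 3 residual degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The median standard error of a log2 fold change was 0.367.

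A total of 34 gene lists were fixed before the data were examined. They cover the sarcomere, chamber and pacemaker markers, ion channels, energy metabolism, stress responses, the cell cycle, cardiac transcription factors, extracellular matrix, sample quality, and markers of heart and non-heart cell types. Lists were tested with camera at a preset correlation between genes of 0.01, which compares a list with all other genes, again with a correlation estimated from the residuals, and with fry. List p-values were adjusted over the 34 lists within a comparison. The level of a list in a library is the mean over its members of the log2 value relative to the gene's mean over the 6 libraries. Members were also tested with adjustment over the list alone.

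Named genes followed a rule fixed at the same time: pitx2; genes past the threshold, up to 10 in each direction, with a mean of at least 50 in the higher group, no overlap between the groups and no clone-type name; where fewer than 10 passed, the genes with the smallest unadjusted p under the same conditions, said not to pass; and per list up to 4 members past the threshold over all genes or otherwise the 2 most abundant. Other genes, including list members that passed only with adjustment over the list alone, are said to have been chosen after their values were seen.

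The procedure was tested on simulated libraries with planted changes. In mutant against WT, 8.96, 64.2 and 86.4% of genes planted at a log2 change of 1, 2 and 3 were recovered. For OE against WT the shares were 8.96, 59.7 and 87.9%, and for OE against mutant 10.4, 76.1 and 86.4%. In the simulation 10, 12 and 16 unchanged genes passed in these comparisons. A planted list shift of -0.5 was found by camera in all 3 comparisons, at the preset and at the estimated correlation, and by fry in 1 of them. Of 33 unshifted lists, camera also called 1 at the preset correlation in OE against WT. At the estimated correlation it called 0 in each comparison. The simulated genes were independent, which real genes are not.

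For the relation of the comparisons with WT, unchanged groups of independent genes were simulated with the spread of each group and put through the same model. Alternatives tried were a fit on the 4 libraries of the groups compared, the replicate number as a block, TMM and quantile rescaling, other filters and pseudocounts, limma without the trend, a threshold of 0.1, a minimum fold, and leaving out each library in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.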

Results

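Gene expression was measured by RNA sequencing in pools of zebrafish hearts at 56 hours post fertilisation, when the heart tube has looped and beats. The 3 groups were pitx2c mutant hearts (mutant), hearts over-expressing pitx2c under the heart muscle promoter myl7 (OE) and wild-type hearts (WT), with 2 pools in each. The comparisons ask how expression in the embryonic heart differs when pitx2c, an isoform of the left-right homeobox gene pitx2, whose human orthologue lies nearest a known atrial fibrillation locus, is mutated or over-expressed. Deposited values summed to 8469703 and 8325928 in mutant, 7474705 and 7370143 in OE, and 8934484 and 8137414 in WT. The WT pools resembled each other less (r = 0.9218 across genes, on the log2 scale) than the mutant pools (0.9568) or the OE pools (0.9398), and WT 1 lay apart from the other 5 libraries on the first principal component, which held 35.68% of the variance (86.67 for WT 1, 7.564 for WT 2, and between -55.36 and 10.76 for the rest). In WT 1 the heart muscle, energy metabolism and endothelial lists were higher than in WT 2, with a sarcomere list level of 0.95 against 0.09 and an oxidative phosphorylation level of 1.15 against 0.02. Erythrocyte and epidermis markers differed within WT as well, at -0.14 and -1.23 for erythrocytes and -0.90 and 0.22 for epidermis.

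pitx2 (ENSDARG00000036194, chromosome 14, 35880165 to 35889514 in GRCz10) was measured in every pool. It stood at 377 and 237 in mutant, 560 and 549 in OE, and 164 and 172 in WT, with means of 307 ± 98.99, 554.5 ± 7.778 and 168 ± 5.657 (SD, n = 2). The log2 difference was 0.83 (SE 0.261) for mutant against WT, 1.72 (SE 0.261) for OE against WT and 0.89 (SE 0.261) for OE against mutant. None of these passed in limma, with adjusted p = 0.562, 0.16 and 0.277, although no pool of one group overlapped another group. Without WT 2, where WT 1 was the lone control, the log2 difference of OE against WT was 1.75. Mutant against WT became 0.49 without mutant 1, and OE against mutant became 0.56 without mutant 2. The gene's count covers all of its transcripts and the type of mutation is not given in the sources used here, so the RNA level does not check the mutant label. Reads from the transgene can add to the OE values.

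In mutant hearts dock11 rose and bcan fell relative to WT. dock11, an exchange factor for the small GTPase Cdc42 (ENSDARG00000062485, chromosome 7, 18927552 to 19080154), stood at 3245 and 5350 in mutant against 115 and 203 in WT. Its means were 4297.5 ± 1488 and 159 ± 62.23 (SD, n = 2), a log2 difference of 4.76 (SE 0.343, limma adjusted p = 0.00792). bcan, which encodes brevican, a proteoglycan of the brain matrix (ENSDARG00000099412, chromosome 16, 29375522 to 29400049), stood at 16 and 10 in mutant against 448 and 427 in WT. Its means were 13 ± 4.243 and 437.5 ± 14.85 (SD, n = 2), a log2 difference of -5.0 (SE 0.303, adjusted p = 0.00425). In OE hearts dock11 stood at 153 and 192 and bcan at 423 and 592. These 2 genes of 18352 tested passed in limma, 1 higher and 1 lower, while 1336 had an unadjusted p under 0.05, 677 higher and 659 lower, where 917.6 are given by chance. The 2 groups did not overlap for 34.97% of genes, where chance gives 33.33%. Without mutant 1 the adjusted p of dock11 was 0.0912, without mutant 2 it was 0.258, without OE 1 0.054 and without OE 2 0.0602. It was 0.0672 in a fit on the 4 mutant and WT libraries and 0.0742 without the trend, where bcan passed (0.0447 and 0.0426). bcan reached 0.101 without mutant 2, and no gene passed then (668 at an unadjusted p under 0.05). Fewer genes passed without mutant 1 or without OE 1, and more without WT 2, where WT 1 was the lone control.

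**Figure D1:**
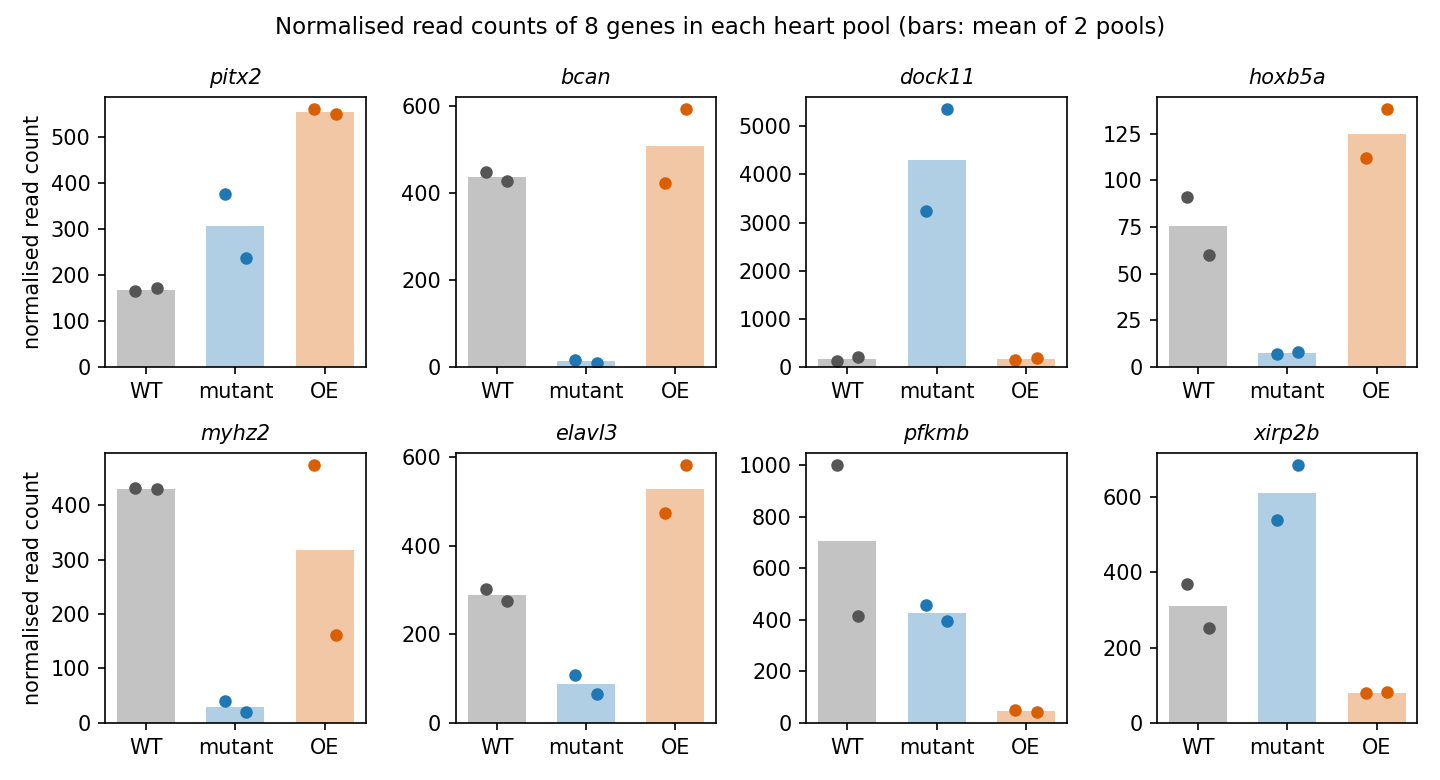
Normalised read count of 8 genes in each heart pool, on linear axes that start at 0, with points for pools and bars for the mean of the 2 pools of a group. dock11 was at 3245 and 5350 in mutant and at most 203 in the other pools, while bcan was at 16 and 10 in mutant and at least 423 in the others.

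Other genes with small unadjusted p in mutant against WT did not pass (limma adjusted p between 0.0941 and 0.182 for the higher genes and between 0.0941 and 0.0974 for the lower). Of the genes higher in mutant, etv2, a transcription factor of endothelial and blood progenitors, stood at 509 and 583 in mutant, 62 and 88 in OE, and 141 and 70 in WT. hbbe3, an embryonic beta globin that can share reads with its paralogues, measured 8019 and 12014 in mutant, 1751 and 6453 in OE, and 1194 and 1164 in WT. myo3a, a class of myosin known from sensory cells, was at 258 and 395 in mutant, 280 and 286 in OE, and 37 and 65 in WT. caspa, an inflammatory caspase, stood at 260 and 304 in mutant, 40 and 42 in OE, and 15 and 40 in WT. zp3d.1 measured 75 and 61 in mutant, 5 and 9 in OE, and 3 and 3 in WT. efcab11 was at 59 and 52 in mutant, 14 and 11 in OE, and 4 and 3 in WT. pip5kl1 stood at 191 and 287 in mutant, 70 and 133 in OE, and 46 and 26 in WT. rfesd measured 318 and 561 in mutant, 267 and 246 in OE, and 119 and 79 in WT. gramd1a was at 663 and 734 in mutant, 399 and 437 in OE, and 313 and 330 in WT. Of the genes lower in mutant, hoxb5a, a trunk homeobox gene, stood at 7 and 8 in mutant, 112 and 138 in OE, and 91 and 60 in WT. myhz2, a fast skeletal myosin with near-identical copies, measured 40 and 20 in mutant, 473 and 161 in OE, and 432 and 429 in WT. smyhc2, a slow skeletal myosin, was at 43 and 56 in mutant, 194 and 145 in OE, and 192 and 254 in WT. pvalb2, a parvalbumin of fast muscle, stood at 38 and 29 in mutant, 145 and 92 in OE, and 279 and 165 in WT. col10a1a, a collagen of cartilage and bone, measured 2 and 6 in mutant, 44 and 30 in OE, and 306 and 89 in WT. f10, coagulation factor X, was at 33 and 35 in mutant, 170 and 126 in OE, and 210 and 160 in WT. mcm6l stood at 20 and 12 in mutant, 4 and 10 in OE, and 869 and 327 in WT. znf1179 measured 16 and 21 in mutant, 124 and 113 in OE, and 131 and 88 in WT. Metazoa_SRP was at 148 and 107 in mutant, 159 and 276 in OE, and 575 and 606 in WT. Skeletal muscle markers as a list were lower in the same pools (median -1.49).

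Skeletal muscle and neuron genes fell in mutant hearts and erythrocyte genes rose, as lists. Of the genes on each list, 36 of 37 skeletal muscle genes were lower (median -1.49, camera adjusted p = 6.16e-29, adjusted p = 0.717 with an estimated correlation, and 25 lower adjusted over the list alone), and 24 of 31 neuron and glia genes were lower (median -0.77, camera adjusted p = 4.58e-09, adjusted p = 0.904 with an estimated correlation, and 9 lower adjusted over the list alone). On the erythrocyte list 21 of 21 genes were higher (median 1.24, camera adjusted p = 2.66e-11, adjusted p = 0.904 with an estimated correlation, and 6 higher adjusted over the list alone). Pigment cell and neural crest genes rose, where 18 of 21 were higher (median 0.48, camera adjusted p = 0.000212, adjusted p = 0.904 with an estimated correlation, and 0 adjusted over the list alone) and liver and yolk genes fell, where 30 of 30 were lower (median -0.67, camera adjusted p = 4.19e-08, adjusted p = 0.904 with an estimated correlation, and 2 lower adjusted over the list alone). Over all genes limma called 0 members of these 5 lists, with 26, 14, 11, 5 and 7 members at an unadjusted p under 0.05. acta1b stood at 2893 and 5137 in mutant, 3278 and 2485 in OE, and 6809 and 3347 in WT. ckma measured 1579 and 1985 in mutant, 663 and 592 in OE, and 3950 and 1652 in WT. nova2 was at 502 and 509 in mutant, 1108 and 897 in OE, and 775 and 531 in WT. tubb5 stood at 359 and 328 in mutant, 944 and 822 in OE, and 617 and 810 in WT. tubb5 was lower in mutant adjusted over the list alone (adjusted p = 0.0153, log2 difference -1.04). Named after their values were seen, fech and gata1a, a heme enzyme and an erythroid factor, were higher adjusted over the list alone (log2 differences 1.89 and 2.25, adjusted p = 0.0118 and 0.0498). hbae3 stood at 38097 and 90569 in mutant, 36789 and 69827 in OE, and 73043 and 21229 in WT. sptb measured 7204 and 13304 in mutant, 3973 and 6996 in OE, and 8239 and 3753 in WT. tfap2a was at 334 and 141 in mutant, 807 and 311 in OE, and 176 and 281 in WT. pmela stood at 253 and 371 in mutant, 276 and 369 in OE, and 215 and 146 in WT. apobb.1 measured 26405 and 19255 in mutant, 26321 and 13489 in OE, and 36286 and 23392 in WT. apoa1b was at 7207 and 6000 in mutant, 9212 and 3989 in OE, and 14201 and 7836 in WT. For erythrocytes the median became 1.91 without mutant 1. For erythrocytes the median became 0.67 without mutant 2. For neurons and glia and pigment cells the median became -0.45 and 0.87 without WT 1. Liver and yolk (-0.22, 0.0551) lost the list call without WT 1, with the median and adjusted p in parentheses. For neurons and glia, erythrocytes and liver and yolk the median became -1.30, 0.72 and -1.09 without WT 2.

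Genes of contraction and energy metabolism were lower in mutant than in WT as lists, and WT 1 held the highest level of each. In the sarcomere list 56 of 65 genes were lower (median -0.25, camera adjusted p = 0.000552, adjusted p = 0.904 with an estimated correlation, and 0 adjusted over the list alone), and 90 of 93 nuclear genes of oxidative phosphorylation were lower (median -0.71, camera adjusted p = 1.07e-19, adjusted p = 0.904 with an estimated correlation, and 0 adjusted over the list alone). For fuel use, 35 of 38 fatty acid oxidation genes were lower (median -0.44, camera adjusted p = 3.98e-07, adjusted p = 0.904 with an estimated correlation, and 0 adjusted over the list alone), 27 of 35 genes of the TCA cycle and pyruvate dehydrogenase were lower (median -0.51, camera adjusted p = 0.000206, adjusted p = 0.904 with an estimated correlation, and 0 adjusted over the list alone) and 31 of 43 glycolysis genes were lower (median -0.47, camera adjusted p = 0.0278, adjusted p = 0.904 with an estimated correlation, and 0 adjusted over the list alone). 41 of 58 ion channel and calcium handling genes were lower (median -0.34, camera adjusted p = 0.0112, adjusted p = 0.904 with an estimated correlation, and 2 lower adjusted over the list alone), and 8 of 9 atrial markers were lower (median -0.31, camera adjusted p = 0.0491, adjusted p = 0.904 with an estimated correlation, and 0 adjusted over the list alone). The ion channel members lower over the list alone, named after their values were seen, were atp2a1 and casq1b, both fast skeletal muscle genes. Over all genes limma called 0 members of these 7 lists, with 8, 11, 4, 3, 3, 4 and 0 at an unadjusted p under 0.05. Sarcomere (0.0034, 0.203), atrial (-0.32, 0.271), ion channels (-0.21, 0.153) and glycolysis (-0.37, 0.143) lost the list call without mutant 1, with the median and adjusted p in parentheses. For sarcomere and atrial the median became -0.47 and -0.60 without mutant 2. Atrial (-0.31, 0.0626) lost the list call without OE 1. Atrial (-0.31, 0.0637) lost the list call without OE 2. Without WT 1 the sarcomere list passed in the opposite direction (median 0.31, adjusted p = 0.0199), and the median of oxidative phosphorylation became -0.14. Atrial (0.12, 0.584), ion channels (0.068, 0.729), glycolysis (0.072, 0.198), the TCA cycle (-0.08, 0.859) and fatty acid oxidation (-0.065, 0.313) lost the list call without WT 1. For sarcomere, atrial, ion channels, glycolysis, the TCA cycle, oxidative phosphorylation and fatty acid oxidation the median became -0.84, -1.10, -0.62, -0.97, -0.95, -1.28 and -0.82 without WT 2. Skeletal muscle and neuron markers moved in the same comparison (medians -1.49 and -0.77).

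Among the remaining lists in mutant against WT, 41 of 52 extracellular matrix genes were lower (median -0.19, camera adjusted p = 0.00723, adjusted p = 0.904 with an estimated correlation, and 0 adjusted over the list alone) and 41 of 56 cell cycle genes were higher (median 0.16, camera adjusted p = 0.0278, adjusted p = 0.904 with an estimated correlation, and 0 adjusted over the list alone). Of the lists on sample handling, 21 of 31 immediate early genes were higher (median 0.27, camera adjusted p = 0.0113, adjusted p = 0.904 with an estimated correlation, and 0 adjusted over the list alone) and 23 of 32 circadian clock genes were lower (median -0.29, camera adjusted p = 0.0337, adjusted p = 0.904 with an estimated correlation, and 0 adjusted over the list alone). Camera did not pass for ventricular (-0.069, 0.619), pacemaker (0.12, 0.493), mitochondrially encoded genes (-0.21, 0.0572), cardiac transcription factors (-0.079, 0.185), nodal signalling (-0.11, 0.444), atrial fibrillation loci (-0.10, 0.355) and endocardium (-0.33, 0.248), given as median and adjusted p. The same was found for epicardium (0.41, 0.895), smooth muscle (-0.0059, 0.619), leukocytes (0.23, 0.493), epidermis (0.10, 0.501), lens (0.55, 0.0508) and cartilage (0.12, 0.395). For the lens and eye list of 7 genes, fry gave an adjusted p of 0.036. Epicardial tgm2b and aldh1a2 were lower adjusted over the list alone (log2 differences -0.95 and -1.06, both adjusted p = 0.0228), and etv2 of the endothelial list was higher (adjusted p = 0.00536). tgm2b stood at 196 and 249 in mutant, 687 and 878 in OE, and 494 and 369 in WT. aldh1a2 measured 128 and 115 in mutant, 224 and 158 in OE, and 244 and 266 in WT. Over all genes limma called 0 members of these lists, while 7 extracellular matrix and 7 immediate early genes had an unadjusted p under 0.05. For immediate early genes the median became 0.47 without mutant 1. Circadian clock (-0.10, 0.276) and cell cycle (0.019, 0.39) lost the list call without mutant 1, with the median and adjusted p in parentheses. Extracellular matrix (-0.20, 0.0763) and immediate early genes (0.079, 0.806) lost the list call without mutant 2. For immediate early genes the median became 0.52 without WT 1. Extracellular matrix (-0.15, 0.0551), the circadian clock (-0.23, 0.162) and cell cycle (-0.12, 0.0868) lost the list call without WT 1. For cell cycle the median became 0.37 without WT 2. Immediate early genes (0.24, 0.424) and the circadian clock (-0.37, 0.0591) lost the list call without WT 2. Cardiac transcription factors (-0.22, 0.0267), endocardium (-0.58, 0.0107), epidermis (0.49, 0.00141) and cartilage (0.64, 0.00273) passed in camera without mutant 2. Lens (0.55, 0.0381) passed in camera without OE 2. Pacemaker (0.45, 0.00399), endocardium (0.24, 0.00223), epidermis (-0.50, 7.72e-06) and cartilage (-0.26, 0.00298) passed in camera without WT 1. Ventricular (-0.70, 0.0155), mitochondrially encoded genes (-0.55, 1.46e-06), cardiac transcription factors (-0.54, 0.000766), atrial fibrillation loci (-0.46, 0.0155), endocardium (-0.81, 2.79e-07), smooth muscle (-0.54, 0.00451), epidermis (0.82, 1.03e-06) and cartilage (0.88, 1.17e-06) passed in camera without WT 2.

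No single gene passed in OE against WT, and the genes with the smallest unadjusted p are given with their values. Of those lower in OE, pfkmb, a muscle phosphofructokinase, stood at 458 and 395 in mutant, 50 and 44 in OE, and 999 and 414 in WT. aldocb, an aldolase, measured 206 and 189 in mutant, 45 and 53 in OE, and 328 and 221 in WT. xirp2b, an actin-binding protein of the intercalated disc, was at 539 and 683 in mutant, 80 and 81 in OE, and 368 and 251 in WT. cx36.7, a connexin of the early heart, stood at 85 and 126 in mutant, 27 and 18 in OE, and 184 and 108 in WT. avpr1aa, a vasopressin receptor, measured 130 and 162 in mutant, 41 and 30 in OE, and 402 and 171 in WT. fgf17, a fibroblast growth factor, was at 70 and 102 in mutant, 13 and 19 in OE, and 193 and 94 in WT. megf6a stood at 172 and 360 in mutant, 41 and 37 in OE, and 549 and 249 in WT. ahrrb measured 6 and 2 in mutant, 4 and 3 in OE, and 147 and 77 in WT. plgrkt was at 146 and 165 in mutant, 56 and 69 in OE, and 227 and 192 in WT. mcm6l was lower as well, at 4 and 10 in OE against 869 and 327 in WT. Of those higher in OE, apart from pitx2, anxa1a, an annexin of the epidermis list, stood at 379 and 229 in mutant, 1009 and 1029 in OE, and 331 and 387 in WT. muc13a, an epithelial mucin, measured 617 and 303 in mutant, 683 and 629 in OE, and 47 and 155 in WT. gria3a, a glutamate receptor subunit, was at 29 and 43 in mutant, 62 and 58 in OE, and 15 and 7 in WT. brsk2b, a kinase of neurons, stood at 37 and 53 in mutant, 165 and 73 in OE, and 21 and 18 in WT. c6, a complement component, measured 103 and 93 in mutant, 219 and 209 in OE, and 97 and 88 in WT. rcvrn2 was at 22 and 22 in mutant, 86 and 31 in OE, and 3 and 7 in WT. ino80e stood at 56 and 35 in mutant, 101 and 158 in OE, and 26 and 36 in WT. nipal4 measured 43 and 36 in mutant, 52 and 96 in OE, and 17 and 14 in WT. myo3a was higher too, at 280 and 286 in OE against 37 and 65 in WT. The log2 difference was -3.75 (SE 0.388) for pfkmb and -2.44 (SE 0.278) for aldocb, both with limma adjusted p = 0.0784. limma called 0 of 18352 genes at the 0.05 threshold, while 2435 had an unadjusted p under 0.05, 1014 higher and 1421 lower, where chance gives 917.6. The groups did not overlap for 40.31% of genes, where chance gives 33.33%. The count rose only with WT 2 left out, where WT 1 was the lone control. WT 1 lay apart from the other libraries on the first principal component, and the spread was then taken from the mutant and OE pools. That count therefore does not show changes that WT 2 had hidden. Neuron and epidermis markers were higher in the same comparison (medians 0.71 and 0.97).

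Genes of heart muscle fell in OE hearts as lists. In the sarcomere list 57 of 65 genes were lower (median -1.31, camera adjusted p = 1.31e-24, adjusted p = 0.422 with an estimated correlation, and 44 lower adjusted over the list alone), and 37 of 58 ion channel and calcium handling genes were lower (median -0.46, camera adjusted p = 6.4e-05, adjusted p = 0.422 with an estimated correlation, and 1 higher and 14 lower adjusted over the list alone). Of the chamber and conduction lists, 6 of 9 ventricular markers were lower (median -1.22, camera adjusted p = 0.0107, adjusted p = 0.519 with an estimated correlation, and 2 higher and 5 lower adjusted over the list alone) and 12 of 18 pacemaker genes were lower (median -0.60, camera adjusted p = 0.00923, adjusted p = 0.515 with an estimated correlation, and 2 higher and 8 lower adjusted over the list alone). 26 of 37 cardiac transcription factor genes were lower (median -0.93, camera adjusted p = 3.12e-06, adjusted p = 0.422 with an estimated correlation, and 2 higher and 11 lower adjusted over the list alone), and 26 of 39 orthologues of atrial fibrillation locus genes were lower (median -0.35, camera adjusted p = 0.000337, adjusted p = 0.422 with an estimated correlation, and 4 lower adjusted over the list alone). Vessel and lining genes fell too, as 27 of 33 endocardial genes were lower (median -0.98, camera adjusted p = 1.08e-07, adjusted p = 0.496 with an estimated correlation, and 2 lower adjusted over the list alone) and 18 of 21 smooth muscle and outflow genes were lower (median -0.97, camera adjusted p = 6.74e-07, adjusted p = 0.422 with an estimated correlation, and 3 lower adjusted over the list alone). Atrial markers did not pass (median -0.79, adjusted p = 0.0511). Over all genes limma called 0 members of these lists, while 47 sarcomere genes had an unadjusted p under 0.05. ttn.2, a titin gene, stood at 105718 and 138314 in mutant, 57533 and 46166 in OE, and 173997 and 92485 in WT. ttn.1, its neighbour, measured 52738 and 70783 in mutant, 23421 and 18055 in OE, and 97370 and 51212 in WT. vmhcl, a ventricular myosin near-identical to vmhc, was at 45414 and 69061 in mutant, 13838 and 8308 in OE, and 105596 and 37462 in WT. vmhc stood at 39125 and 60141 in mutant, 24503 and 19425 in OE, and 80204 and 32276 in WT. myh6, the atrial myosin, measured 13207 and 17422 in mutant, 9940 and 8065 in OE, and 35923 and 13117 in WT. nppa, a natriuretic peptide gene, was at 6078 and 9547 in mutant, 5563 and 4395 in OE, and 16363 and 5470 in WT. cacna1g, a T-type calcium channel, stood at 2287 and 2995 in mutant, 732 and 772 in OE, and 3029 and 1756 in WT. bmp4, a secreted signal, measured 725 and 1022 in mutant, 453 and 333 in OE, and 1195 and 631 in WT. ryr2b, the cardiac ryanodine receptor, was at 6186 and 9448 in mutant, 2318 and 2509 in OE, and 13383 and 5029 in WT. slc8a1a, the sodium-calcium exchanger, stood at 6622 and 8414 in mutant, 3275 and 3000 in OE, and 11971 and 5153 in WT. zfhx3 stood at 2835 and 2424 in mutant, 2950 and 2919 in OE, and 2325 and 2811 in WT. gata5 measured 1087 and 1571 in mutant, 799 and 562 in OE, and 2681 and 891 in WT. notch1b was at 2567 and 3937 in mutant, 2296 and 1751 in OE, and 6953 and 2878 in WT. cdh5 stood at 1670 and 2436 in mutant, 1395 and 1296 in OE, and 6106 and 2062 in WT. myl9b measured 2343 and 2233 in mutant, 1586 and 1281 in OE, and 4300 and 2344 in WT. desma was at 1819 and 2992 in mutant, 884 and 761 in OE, and 3218 and 1705 in WT. Of these, ttn.2, ttn.1, vmhcl, vmhc, cacna1g, bmp4, ryr2b, slc8a1a, myl9b and desma were lower in OE adjusted over the list alone. Named after their values were seen, mybpc3, csrp3 and the pacemaker channel hcn4 were lower on the same terms. mybpc3 stood at 7570 and 10026 in mutant, 1964 and 1405 in OE, and 15803 and 6233 in WT. csrp3 measured 244 and 371 in mutant, 48 and 17 in OE, and 1013 and 298 in WT. hcn4 was at 806 and 719 in mutant, 152 and 63 in OE, and 959 and 343 in WT. Members higher in OE on those terms, also named after their values were seen, were irx4b and irx1b among ventricular markers and isl1 among cardiac transcription factors and pacemaker genes. For sarcomere, cardiac transcription factors, smooth muscle and endocardium the median became -0.79, -0.42, -0.39 and -0.40 without WT 1. Ventricular (-0.56, 0.0726) and pacemaker (-0.22, 0.194) lost the list call without WT 1, with the median and adjusted p in parentheses. For sarcomere, ventricular, cardiac transcription factors, atrial fibrillation loci, smooth muscle and endocardium the median became -1.97, -1.88, -1.48, -0.70, -1.48 and -1.59 without WT 2. Atrial (-0.79, 0.0473) passed in camera without mutant 1. Atrial (-0.79, 0.0488) passed in camera without mutant 2. Atrial (-1.40, 0.00142) passed in camera without WT 2. Epidermis (median 0.97) and neuron markers (0.71) were higher and skeletal muscle markers (-0.51) lower in the same pools.

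Energy metabolism genes fell in OE hearts as lists. In glycolysis 33 of 43 genes were lower (median -1.15, camera adjusted p = 6.08e-11, adjusted p = 0.422 with an estimated correlation, and 24 lower adjusted over the list alone), and 92 of 93 nuclear genes of oxidative phosphorylation were lower (median -1.01, camera adjusted p = 4.97e-26, adjusted p = 0.422 with an estimated correlation, and 3 lower adjusted over the list alone). For the mitochondrial genome, 13 of 13 mitochondrially encoded genes were lower (median -0.72, camera adjusted p = 1.35e-07, adjusted p = 0.422 with an estimated correlation, and 0 adjusted over the list alone). In addition, 31 of 35 TCA cycle genes were lower (median -0.97, camera adjusted p = 6.08e-11, adjusted p = 0.422 with an estimated correlation, and 0 adjusted over the list alone), 34 of 38 fatty acid oxidation genes were lower (median -0.77, camera adjusted p = 3.29e-11, adjusted p = 0.422 with an estimated correlation, and 12 lower adjusted over the list alone) and 28 of 29 heat shock genes were lower (median -0.65, camera adjusted p = 4.13e-07, adjusted p = 0.422 with an estimated correlation, and 4 lower adjusted over the list alone). Over all genes limma called 0 members of these lists, while 25 glycolysis and 59 oxidative phosphorylation genes had an unadjusted p under 0.05. gapdh, a glycolytic enzyme, stood at 3838 and 4159 in mutant, 2113 and 1354 in OE, and 9413 and 3422 in WT. aldoaa, an aldolase, measured 2254 and 2597 in mutant, 1409 and 1022 in OE, and 5057 and 2224 in WT. atp5a1, an ATP synthase subunit, was at 2785 and 2855 in mutant, 2466 and 1898 in OE, and 6089 and 2957 in WT. atp5b, another, stood at 2721 and 2471 in mutant, 2264 and 1742 in OE, and 5112 and 2724 in WT. mt-co1, a cytochrome oxidase subunit, measured 32103 and 30643 in mutant, 27147 and 25984 in OE, and 48917 and 28980 in WT. mt-co2 was at 12009 and 11912 in mutant, 9651 and 8500 in OE, and 17549 and 10866 in WT. IDH2 stood at 2131 and 2503 in mutant, 1871 and 1311 in OE, and 4652 and 2414 in WT. aco2 measured 1432 and 1424 in mutant, 1158 and 850 in OE, and 3670 and 1545 in WT. acsl1b, an acyl-CoA synthetase, was at 1702 and 1396 in mutant, 756 and 549 in OE, and 2513 and 1285 in WT. acadvl stood at 671 and 620 in mutant, 681 and 497 in OE, and 1881 and 713 in WT. Of these, gapdh, aldoaa and acsl1b were lower in OE adjusted over the list alone (adjusted p = 0.0128, 0.0128 and 0.0214). For glycolysis, the TCA cycle, oxidative phosphorylation, mitochondrially encoded genes and fatty acid oxidation the median became -0.75, -0.44, -0.45, -0.35 and -0.35 without WT 1. For glycolysis, oxidative phosphorylation and fatty acid oxidation the median became -1.72, -1.58 and -1.25 without WT 2. Epidermis and neuron markers were higher in the same pools (medians 0.97 and 0.71).

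Markers of several tissues outside the heart muscle rose in OE hearts as lists. For the nervous system and skin, 28 of 31 neuron and glia genes were higher (median 0.71, camera adjusted p = 6.74e-07, adjusted p = 0.422 with an estimated correlation, and 1 higher adjusted over the list alone) and 35 of 38 epidermis genes were higher (median 0.97, camera adjusted p = 2.93e-10, adjusted p = 0.422 with an estimated correlation, and 2 higher adjusted over the list alone). For blood, 20 of 21 erythrocyte genes were higher (median 0.91, camera adjusted p = 4.08e-05, adjusted p = 0.515 with an estimated correlation, and 0 adjusted over the list alone) and 20 of 24 leukocyte genes were higher (median 0.59, camera adjusted p = 0.0107, adjusted p = 0.497 with an estimated correlation, and 0 adjusted over the list alone). 18 of 21 pigment cell and neural crest genes were higher (median 0.83, camera adjusted p = 2.51e-05, adjusted p = 0.422 with an estimated correlation, and 0 adjusted over the list alone). Skeletal muscle and liver genes fell, as 30 of 37 skeletal muscle genes were lower (median -0.51, camera adjusted p = 8.13e-06, adjusted p = 0.422 with an estimated correlation, and 2 lower adjusted over the list alone) and 26 of 30 liver and yolk genes were lower (median -0.72, camera adjusted p = 1.45e-06, adjusted p = 0.497 with an estimated correlation, and 0 adjusted over the list alone). Over all genes limma called 0 members of these lists, while 17 epidermis and 10 neuron genes had an unadjusted p under 0.05. krt4, a keratin, stood at 46311 and 18884 in mutant, 70693 and 55990 in OE, and 10084 and 46794 in WT. krt8 measured 7543 and 8157 in mutant, 8311 and 7808 in OE, and 8574 and 6309 in WT. apoc1 was at 1013 and 1331 in mutant, 1503 and 671 in OE, and 2595 and 1421 in WT. s100a10b stood at 512 and 453 in mutant, 676 and 650 in OE, and 769 and 540 in WT. Camera did not pass for epicardium (0.46, 0.214), lens (0.54, 0.0773), cartilage (0.45, 0.0935) and nodal signalling (-0.24, 0.0935), given as median and adjusted p. For erythrocytes, skeletal muscle and liver and yolk the median became 1.41, -0.80 and -1.11 without OE 1. For pigment cells and skeletal muscle the median became 0.51 and -0.24 without OE 2. Erythrocytes (0.33, 0.0504), leukocytes (0.15, 0.472) and liver and yolk (-0.20, 0.119) lost the list call without OE 2, with the median and adjusted p in parentheses. For neurons and glia, epidermis, erythrocytes and liver and yolk the median became 1.21, 0.37, 1.44 and -0.30 without WT 1. For neurons and glia, epidermis and liver and yolk the median became 0.44, 1.62 and -1.18 without WT 2. Erythrocytes (0.33, 0.442) and leukocytes (0.63, 0.278) lost the list call without WT 2. Cartilage (0.69, 0.0359) passed in camera without OE 2. Epicardium (0.54, 0.0119) passed in camera without WT 1. Cartilage (1.55, 1.61e-06) passed in camera without WT 2.

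**Figure D2:**
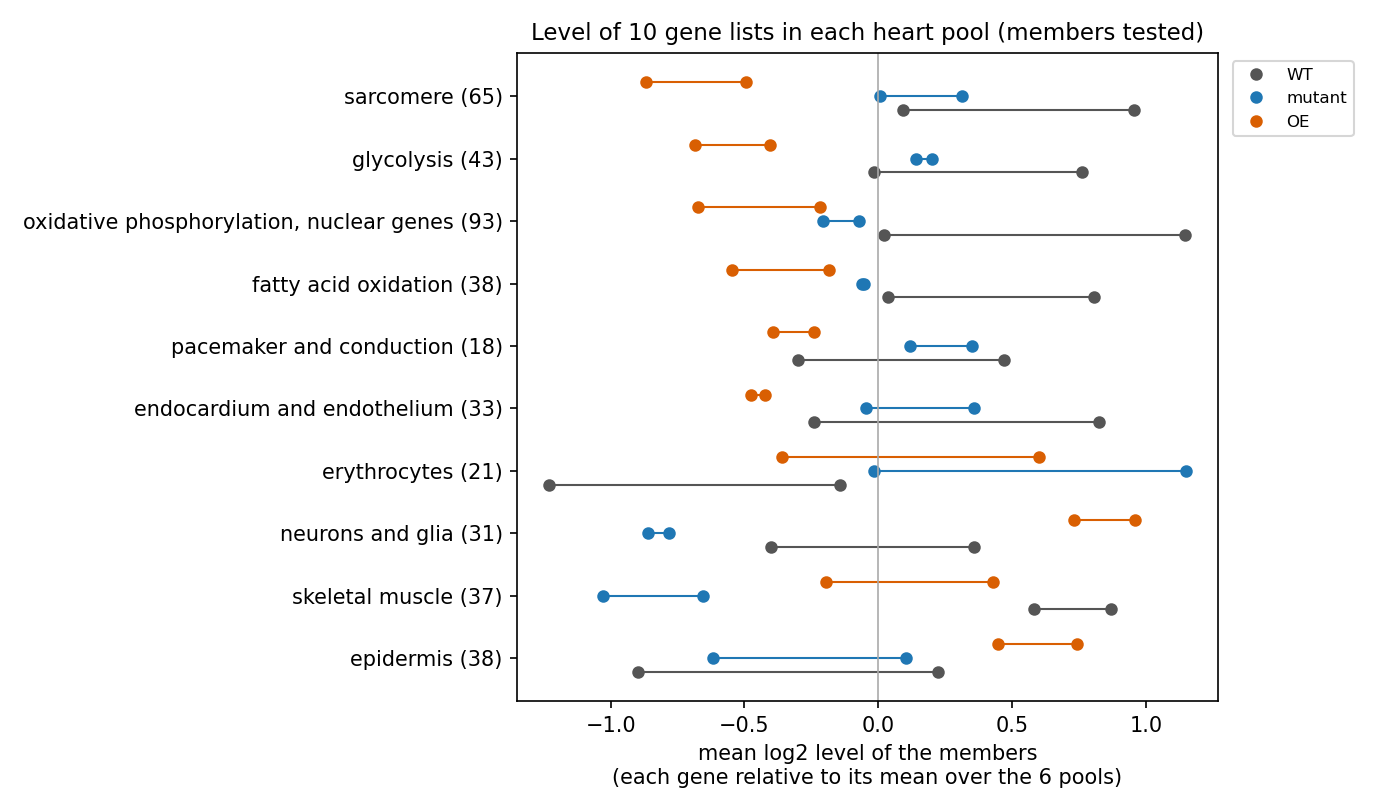
Level of 10 gene lists in each heart pool, as the mean over members of the log2 value relative to the gene's mean over the 6 pools, with a point per pool and a line joining the 2 pools of a group. Both OE pools lie below the other pools for the sarcomere list, at -0.49 and -0.87, and both mutant pools lie below the others for skeletal muscle, at -0.66 and -1.03.

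Compared with mutant hearts, bcan, stmn1b, elavl3, scrt1a, hoxb5a and hoxc4a were higher in OE with 4 genes of clone-type names, and dock11, and2 and xirp2b were lower. OE values of bcan (423 and 592) and dock11 (153 and 192) lay near those of WT (448 and 427, and 115 and 203). Their differences here thus came from the mutant values. bcan was higher by a log2 difference of 5.2 (SE 0.303, limma adjusted p = 0.00318), at 13 ± 4.243 in mutant and 507.5 ± 119.5 in OE (SD, n = 2). stmn1b and elavl3, a stathmin and an RNA-binding protein of neurons, were higher by 3.34 (SE 0.312, adjusted p = 0.0222) and 2.61 (SE 0.287, adjusted p = 0.0347). The trunk homeobox genes hoxb5a and hoxc4a were higher by 3.89 (SE 0.363, adjusted p = 0.0222) and 4.46 (SE 0.457, adjusted p = 0.0273). hoxb5a stood at 7 and 8 in mutant, 112 and 138 in OE, and 91 and 60 in WT. scrt1a, a transcription repressor of neurons, was higher by 4.81 (SE 0.564, adjusted p = 0.0479). xirp2b, an actin-binding protein of the intercalated disc, had a log2 difference of -2.90 (SE 0.262, adjusted p = 0.0222). dock11 had -4.60 (SE 0.343, adjusted p = 0.0103), and and2, an actinodin of the fin fold, had -4.11 (SE 0.456, adjusted p = 0.0347). stmn1b stood at 33 and 33 in mutant, 404 and 290 in OE, and 194 and 123 in WT. elavl3 measured 109 and 66 in mutant, 473 and 581 in OE, and 302 and 274 in WT. hoxc4a was at 2 and 2 in mutant, 57 and 74 in OE, and 40 and 30 in WT. scrt1a stood at 1 and 3 in mutant, 71 and 86 in OE, and 31 and 17 in WT. and2 measured 218 and 375 in mutant, 10 and 24 in OE, and 109 and 84 in WT. limma called 13 genes, 10 higher and 3 lower in OE, 4 of them with clone-type names, and 1878 had an unadjusted p under 0.05, 914 higher and 964 lower. The groups did not overlap for 44.0% of genes, where chance gives 33.33%. limma called 1 gene without mutant 1, which was bcan (adjusted p = 0.0359), and 0 without mutant 2, without OE 1 and without OE 2 (879, 1176 and 1344 at an unadjusted p under 0.05). It called 295 without WT 1 and 321 without WT 2, and both sets held the same 13 genes. With the replicate number as a block bcan and dock11 passed (limma adjusted p = 0.0141 and 0.0065). The adjusted p was then 0.0738 for stmn1b, 0.0763 for hoxb5a, and2 and xirp2b, 0.0833 for elavl3 and hoxc4a and 0.0968 for scrt1a. Without the trend the adjusted p was 0.0759 for hoxb5a, 0.0974 for stmn1b, scrt1a, dock11 and xirp2b, 0.127 for and2 and 0.134 for elavl3. Among genes with a mean of at least 50 it was 0.0608 for hoxb5a and elavl3 and 0.0609 for and2, and with a pseudocount of 0.5 it was 0.0549 for scrt1a. Genes that did not pass but had small unadjusted p were, with higher values in OE, znf1179, stmn2b, basp1 and tgm2b (adjusted p between 0.0579 and 0.085). With lower values in OE they were pfkmb, etv2, aldocb, ldb3b, pde3a, cacna1g and atp6ap1a (adjusted p between 0.0566 and 0.0936). stmn2b, a stathmin of neurons, stood at 18 and 8 in mutant, 176 and 105 in OE, and 92 and 65 in WT. basp1, a growth cone protein, measured 39 and 39 in mutant, 175 and 142 in OE, and 85 and 82 in WT. ldb3b, a Z-disc protein, was at 826 and 1082 in mutant, 164 and 167 in OE, and 1302 and 588 in WT. pde3a, a phosphodiesterase, stood at 686 and 707 in mutant, 300 and 287 in OE, and 668 and 601 in WT. atp6ap1a measured 253 and 367 in mutant, 92 and 65 in OE, and 143 and 104 in WT. Neuron markers were higher in both OE pools than in both mutant pools, with list levels of 0.96 and 0.73 against -0.86 and -0.78.

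As lists, neuron, skeletal muscle and epidermis genes were higher in OE than in mutant hearts, and heart muscle, vessel and glycolysis genes were lower. On the neuron list 29 of 31 genes were higher (median 1.59, camera adjusted p = 2.44e-20, adjusted p = 0.784 with an estimated correlation, and 17 higher adjusted over the list alone), with 2 called over all genes, stmn1b and elavl3. For other tissues, 30 of 37 skeletal muscle genes were higher (median 1.0, camera adjusted p = 1.23e-11, adjusted p = 0.784 with an estimated correlation, and 15 higher and 1 lower adjusted over the list alone) and 35 of 38 epidermis genes were higher (median 0.83, camera adjusted p = 1.03e-09, adjusted p = 0.784 with an estimated correlation, and 1 higher adjusted over the list alone). In the heart, 52 of 65 sarcomere genes were lower (median -1.10, camera adjusted p = 7.66e-16, adjusted p = 0.784 with an estimated correlation, and 4 higher and 33 lower adjusted over the list alone), 14 of 18 pacemaker genes were lower (median -0.56, camera adjusted p = 0.00082, adjusted p = 0.791 with an estimated correlation, and 4 lower adjusted over the list alone) and 6 of 9 ventricular markers were lower (median -1.14, camera adjusted p = 0.0273, adjusted p = 0.805 with an estimated correlation, and 1 higher and 3 lower adjusted over the list alone). Furthermore, 33 of 43 glycolysis genes were lower (median -0.81, camera adjusted p = 5.1e-09, adjusted p = 0.784 with an estimated correlation, and 5 lower adjusted over the list alone), 21 of 21 smooth muscle and outflow genes were lower (median -0.68, camera adjusted p = 1.03e-06, adjusted p = 0.784 with an estimated correlation, and 3 lower adjusted over the list alone) and 30 of 33 endocardial genes were lower (median -0.63, camera adjusted p = 1.03e-06, adjusted p = 0.805 with an estimated correlation, and 1 lower adjusted over the list alone). The sarcomere genes higher in OE over the list alone, named after their values were seen, were myl10, myl4, mybpha and tnnt2c. The skeletal muscle gene lower in OE was ckma (adjusted over the list alone, adjusted p = 0.0139). Apart from the neuron list, limma called 0 members of these lists over all genes, while 44 sarcomere and 20 skeletal muscle genes had an unadjusted p under 0.05. For epidermis the median became 1.25 without mutant 1. For epidermis and endocardium the median became 0.44 and -0.36 without mutant 2. Ventricular (-0.84, 0.194) lost the list call without mutant 2, with the median and adjusted p in parentheses. Ventricular (-0.95, 0.117) lost the list call without OE 2.

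Energy genes other than glycolysis were also lower in OE than in mutant hearts as lists at the preset correlation. The list medians were -0.36 for the TCA cycle (camera adjusted p = 0.00011, adjusted p = 0.805 with an estimated correlation), -0.30 for oxidative phosphorylation (camera adjusted p = 0.000315, adjusted p = 0.805 with an estimated correlation), -0.50 for mitochondrially encoded genes (camera adjusted p = 4.9e-05, adjusted p = 0.805 with an estimated correlation) and -0.20 for fatty acid oxidation (camera adjusted p = 0.00334, adjusted p = 0.805 with an estimated correlation). For the other lists that passed they were -0.55 for heat shock (adjusted p = 1.08e-06, adjusted p = 0.784 with an estimated correlation), -0.33 for cardiac transcription factors (adjusted p = 0.000333, adjusted p = 0.784 with an estimated correlation), -0.24 for atrial fibrillation loci (adjusted p = 0.00334, adjusted p = 0.784 with an estimated correlation) and -0.31 for erythrocytes (adjusted p = 0.0159, adjusted p = 0.805 with an estimated correlation). limma called 0 members of these lists over all genes, while 13 cardiac transcription factor genes had an unadjusted p under 0.05. Adjusted over the list alone, 2 heat shock genes and 1 atrial fibrillation locus gene were lower. Of 58 ion channel and calcium handling genes, 6 were higher and 10 lower on the same terms, with 20 at an unadjusted p under 0.05. Among the 10 were ryr2b and slc8a1a and, named after their values were seen, cacna1c, trdn and pln, and among the 6 were the sodium pump subunits atp1a3a and atp1b1b and the skeletal muscle gene atp2a1. Over the list alone meis2b of the atrial list, also named after its values were seen, was higher in OE (log2 difference 1.45, adjusted p = 0.0297), as was tgm2b of the epicardium list (1.81, adjusted p = 0.000825). Camera did not pass for atrial (-0.18, 0.806), ion channels (-0.30, 0.0509), nodal signalling (-0.14, 0.422), extracellular matrix (0.08, 0.966), cell cycle (0.13, 0.17) and epicardium (0.0066, 0.422), given as median and adjusted p. Among cell types it did not pass for leukocytes (0.22, 0.0615), pigment cells (0.061, 0.355), liver and yolk (-0.12, 0.966), lens (-0.0094, 0.94) and cartilage (0.20, 0.422). For cardiac transcription factors, atrial fibrillation loci and erythrocytes the median became -0.59, -0.55 and -0.95 without mutant 1. Erythrocytes (0.18, 0.773) lost the list call without mutant 2, with the median and adjusted p in parentheses. For the TCA cycle, oxidative phosphorylation and fatty acid oxidation the median became -0.64, -0.56 and -0.44 without OE 1. Erythrocytes (0.12, 0.916) lost the list call without OE 1. For the TCA cycle, cardiac transcription factors, atrial fibrillation loci and erythrocytes the median became -0.23, -0.49, -0.45 and -0.80 without OE 2. Oxidative phosphorylation (-0.053, 0.527) and fatty acid oxidation (-0.035, 0.372) lost the list call without OE 2. Ion channels (-0.40, 0.0203), cell cycle (0.21, 0.0299) and cartilage (0.63, 0.00734) passed in camera without mutant 1. Leukocytes (0.42, 0.00318) passed in camera without mutant 2. Leukocytes (0.56, 0.000467), pigment cells (0.39, 0.00974) and liver and yolk (-0.53, 0.000686) passed in camera without OE 1. Cell cycle (0.23, 0.00899) and liver and yolk (0.47, 0.000659) passed in camera without OE 2. Ion channels (-0.30, 0.00466) passed in camera without WT 1. Ion channels (-0.30, 0.00703) passed in camera without WT 2. Neuron markers moved in the same comparison (median 1.59).

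Camera at the preset correlation called 16, 24 and 17 of the 34 lists in mutant against WT, OE against WT and OE against mutant. With an estimated correlation it called 0 in each, with smallest adjusted p = 0.717, 0.422 and 0.784. The estimated correlation was 0.495 for sarcomere, 0.76 for oxidative phosphorylation and 0.975 for mitochondrially encoded genes. Camera p-values at the preset of 0.01 take genes as almost independent, so they do not measure the spread between pools. fry called 1, 0 and 0, with smallest adjusted p = 0.036, 0.291 and 0.276. Its mixed test, for change in either direction, called 2, 0 and 1, which were epicardium (adjusted p = 0.0145) and lens (0.0105) in mutant against WT and epicardium (0.00296) in OE against mutant. The list median and camera differed in sign for 0, 3 and 2 lists and the list mean and camera for 3, 2 and 2. For the extracellular matrix list in OE against WT the median was 0.0083 and the mean -0.32, while camera gave a fall (adjusted p = 0.0392, adjusted p = 0.519 with an estimated correlation). Extracellular matrix (0.0083, 0.0503) lost the list call without mutant 1, with the median and adjusted p in parentheses. Extracellular matrix (0.0083, 0.0531) lost the list call without mutant 2. For extracellular matrix the median became -0.13 without OE 1. Extracellular matrix (0.13, 0.467) lost the list call without OE 2. For extracellular matrix the median became -0.087 without WT 1. Extracellular matrix (-0.029, 0.0829) lost the list call without WT 2.

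The 2 comparisons with WT share their control pools. Across 18352 genes, which are not independent replicates, their log2 differences had r = 0.522 and rho = 0.511. In 100 simulations of unchanged groups against the same controls the values were 0.634 and 0.597. The covariance was 0.2765 against 0.1631 simulated, a difference of 0.113. At an unadjusted p under 0.05 in both, 257 genes were higher in both, where the simulations gave a mean of 167 (134 to 207) and independent lists give 37.4. Lower in both were 181, where the simulations gave 191 (152 to 221) and independent lists give 51.0. Genes that were higher in mutant and lower in OE numbered 6, where the simulations gave 0.5 and independent lists give 52.4, and those lower in mutant and higher in OE numbered 33, where they gave 0.74 and give 36.4. The simulated genes were independent, which real genes are not. The simulated ranges are therefore too narrow to judge these counts by. The WT pools are too few to be split, so part of these overlaps can come from the shared controls. r was 0.387 without OE 2 and 0.723 without WT 2. Among gene lists, neuron genes were lower in mutant (median -0.77) and higher in OE (0.71), and their difference between OE and mutant was tested directly (median 1.59, camera adjusted p = 2.44e-20, adjusted p = 0.784 with an estimated correlation).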

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

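The settings were planned before the values were seen. In mutant against WT limma called 2 genes, and 20 at an adjusted p under 0.1, 12 with no filter, 4 without the trend and 0 to 32 with 1 library left out. The fit on 4 libraries called 2, both lower, and it and the fit without the trend each held bcan and not dock11 of the 2 genes. In OE against WT it called 0 (2435 at an unadjusted p under 0.05), and 6 at an adjusted p under 0.1, 1 after quantile normalisation, 2 with no filter and 0 to 1612 with 1 library left out. In OE against mutant it called 13, and 83 at an adjusted p under 0.1, 291 on the 4 libraries of the 2 groups, 26 after quantile normalisation, 5 with a mean of at least 50, 3 without the trend, of which bcan and hoxc4a were among the 13, and 0 to 321 with 1 library left out. With the replicate block it called 2 in OE against mutant, bcan and dock11. Whether the replicate numbers pair the pools is not known. Deviations of same-numbered pools correlated at 0.0903 for mutant and OE, -0.238 for mutant and WT and 0.0492 for OE and WT. Such weak correlations over all genes do not exclude pairing. Genes at 0 numbered 1039 in mutant 1 and 1015 in OE 1, and 364 in mutant 2 and 370 in OE 2. TMM and the other pseudocounts kept each count within 1.5 times. Lists called numbered 0, 0 and 0 with an estimated correlation and 1, 0 and 0 with fry, for mutant against WT, OE against WT and OE against mutant. The cause of these changes was not tested. Fewer libraries leave fewer degrees of freedom, and a lone pool is assumed to vary like the other groups. Fewer degrees of freedom do not account for the rise to 291 in OE against mutant, in the fit without the WT libraries. The mean variance within a group was 0.4106 in WT, 0.2065 in mutant and 0.2697 in OE. With 1 library left out pitx2 ranged from 1.68 to 1.75 in OE against WT, where it passed without WT 2, from 0.49 to 1.16 in mutant against WT and from 0.56 to 1.2 in OE against mutant. The correlation of the comparisons with WT ranged from 0.387 to 0.723. List medians that turned direction with 1 library left out, with a call before or after, ranged, in mutant against WT, from -0.84 to 0.31 for sarcomere, -1.10 to 0.12 for atrial, -0.62 to 0.068 for ion channels, -0.97 to 0.072 for glycolysis, -0.12 to 0.37 for cell cycle, -0.81 to 0.24 for endocardium, -0.50 to 0.82 for epidermis and -0.26 to 0.88 for cartilage. In OE against WT the range was -0.0064 to 0.46 for cell cycle, -0.13 to 0.13 for extracellular matrix and -0.24 to 0.14 for the circadian clock, and in OE against mutant -0.33 to 0.22 for immediate early genes, -0.95 to 0.18 for erythrocytes and -0.53 to 0.47 for liver and yolk. Ribosomal proteins in OE against WT reached 0.20 after quantile normalisation, from -0.032. Over single lists, 246 values of called lists in OE against WT kept direction and side of the threshold, 65 lost the call and 1 turned direction in camera, against 149, 54 and 5 in mutant against WT and 180, 40 and 1 in OE against mutant. Not run were the planned count tests, since the values are normalised, and the lens list has no value with a mean of at least 50. The estimated read totals, between 6900000 and 10200000, limit low genes most.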

Other observations

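All tests of an explanation in this part were chosen after the results were seen.

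Stress and housekeeping lists did not pass in mutant hearts, and their medians moved with single pools. Camera did not pass in mutant against WT for heat shock (-0.055, 0.593), unfolded protein stress (-0.15, 0.337), antioxidant genes (-0.028, 0.493), p53 targets (-0.023, 0.992) and ribosomal proteins (-0.059, 0.41), given as median log2 difference and adjusted p. With 1 library left out p53 targets ranged from -0.29 (without WT 2) to 0.30 (without WT 1), antioxidant genes from -0.33 (without WT 2) to 0.12 (without WT 1) and heat shock from -0.30 (without mutant 1) to 0.012 (without WT 1). Unfolded protein stress ranged from -0.18 (without WT 1) to -0.036 (without mutant 2) and ribosomal proteins from -0.16 (without mutant 1) to 0.04 (without mutant 2). In OE against WT it did not pass for unfolded protein stress (-0.21, 0.204), antioxidant genes (0.0051, 0.621), p53 targets (-0.13, 0.172), ribosomal proteins (-0.032, 0.893) and the circadian clock (0.02, 0.893). In OE against mutant it did not pass for unfolded protein stress (-0.042, 0.94), antioxidant genes (-0.053, 0.94), p53 targets (-0.16, 0.232), ribosomal proteins (0.031, 0.465), immediate early genes (0.037, 0.94) and the circadian clock (0.18, 0.0558). Immediate early genes, which dissection can induce, rose in OE against WT (median 0.51, camera adjusted p = 0.0184, adjusted p = 0.565 with an estimated correlation), as did cell cycle genes (0.24, adjusted p = 0.000329, adjusted p = 0.565 with an estimated correlation). limma called 0 members of these lists over all genes, with 9 immediate early and 2 cell cycle genes at an unadjusted p under 0.05 in OE against WT. Cell cycle (0.13, 0.107) lost the list call without OE 1, with the median and adjusted p in parentheses. Immediate early genes (0.21, 0.336) lost the list call without OE 2. Cell cycle (-0.0064, 0.84) lost the list call without WT 1. For cell cycle the median became 0.46 without WT 2. Immediate early genes (0.36, 0.48) lost the list call without WT 2. In the same comparison the circadian clock (-0.24, 0.0427) passed in camera without OE 1 and p53 targets (-0.35, 0.0151) passed in camera without WT 2. In mutant against WT ribosomal proteins (-0.16, 0.0111) passed in camera without mutant 1. In OE against mutant ribosomal proteins (0.12, 0.0168) and immediate early genes (-0.33, 0.0295) passed in camera without mutant 1, immediate early genes (0.22, 0.0151) and the circadian clock (0.30, 0.00212) passed in camera without mutant 2, and ribosomal proteins (0.12, 0.0422) and the circadian clock (0.47, 0.000619) passed in camera without OE 2. hspa8, a constitutive chaperone, stood at 30553 and 27703 in mutant, 30095 and 26836 in OE, and 35676 and 32097 in WT. hsp90ab1 measured 24270 and 22163 in mutant, 21638 and 18194 in OE, and 20556 and 23391 in WT. hsp90b1 was at 3175 and 1913 in mutant, 3009 and 2040 in OE, and 2908 and 3364 in WT. canx stood at 2611 and 1749 in mutant, 2663 and 1999 in OE, and 2564 and 2785 in WT. prdx2, a peroxiredoxin abundant in red cells, measured 1375 and 2448 in mutant, 1901 and 3303 in OE, and 1643 and 1117 in WT. gpx4a was at 612 and 481 in mutant, 486 and 306 in OE, and 1418 and 508 in WT. ccng1 stood at 1827 and 1638 in mutant, 1245 and 1128 in OE, and 2144 and 1534 in WT. foxo3b measured 818 and 1439 in mutant, 940 and 967 in OE, and 1092 and 831 in WT.

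rpl4 stood at 9527 and 8971 in mutant, 9145 and 8059 in OE, and 8499 and 9461 in WT. rps2 measured 9912 and 9104 in mutant, 9176 and 8271 in OE, and 8041 and 8990 in WT. hmgb2a, a chromatin protein of dividing cells, was at 3265 and 3017 in mutant, 4399 and 3540 in OE, and 2918 and 3557 in WT. mki67 stood at 3785 and 3361 in mutant, 3963 and 3457 in OE, and 2158 and 3832 in WT. btg1 measured 2866 and 3232 in mutant, 2743 and 2153 in OE, and 3925 and 2284 in WT. jun was at 639 and 790 in mutant, 668 and 618 in OE, and 740 and 761 in WT. cry1ba stood at 1191 and 991 in mutant, 1266 and 779 in OE, and 1468 and 1225 in WT. nfil3-5 measured 481 and 398 in mutant, 831 and 529 in OE, and 342 and 530 in WT. acvr1ba was at 433 and 421 in mutant, 479 and 368 in OE, and 539 and 386 in WT. col1a1b stood at 7278 and 4108 in mutant, 8071 and 6835 in OE, and 6046 and 7137 in WT. col1a1a measured 6622 and 4141 in mutant, 7450 and 6542 in OE, and 5263 and 7279 in WT. mipa was at 38 and 40 in mutant, 25 and 40 in OE, and 25 and 28 in WT. pde6d stood at 26 and 9 in mutant, 33 and 17 in OE, and 19 and 16 in WT. col11a1a measured 3365 and 1246 in mutant, 3424 and 2708 in OE, and 1214 and 3700 in WT. col2a1a was at 2498 and 429 in mutant, 2888 and 1396 in OE, and 618 and 4396 in WT.

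The first pattern is the lower level of sarcomere genes in OE than in WT (median -1.31), which tissue from outside the heart, a lower share of heart muscle cells, or WT 1 may account for. If 1 source of tissue that raises neuron and skeletal muscle genes in equal measure diluted the OE pools, the 2 lists would rise alike. A source rich in only one of these tissues would not raise them alike, so the test cannot decide on dilution in general. The difference of their levels was higher in OE than in WT by 1.48 (95% interval 0.482 to 2.47). Over the 36 choices of 2 lists its adjusted p was 0.324. The interval excluded 0 for 3 choices, each with skeletal muscle or liver and yolk. The neuron list changed by less than the standard error against epidermis (-0.0634, SE 0.834), erythrocytes (0.0621, SE 0.671), pigment cells (0.0881, SE 0.34), lens (0.00581, SE 0.398) and cartilage (0.36, SE 1.08). It changed by more than the standard error against leukocytes (0.426, SE 0.405) and liver and yolk (1.58, SE 0.323). Dilution stays open. Relative to the 10 most abundant sarcomere genes, 6 of 65 members were lower in OE and 1 higher adjusted over the list alone. Among the 6 was vmhcl, which is itself among the 10 reference genes. With all members as the reference, the version run first, 1 was lower (csrp3) and 1 higher (tmod4), also adjusted over the list alone. That version was fitted over all genes tested, with 3012 called. It thus differed in more than the reference, and the smaller count cannot be credited to the reference alone. In OE against mutant 7 were lower and 12 higher relative to the 10. Since the counts depend on the version, a lower muscle share stays open. Against the mutant, which leaves out the WT levels but not their spread, 33 of 65 members were lower in OE adjusted over the list alone (46 lower and 5 higher with WT 1 left out), a test changed from one on the list level (-0.84, 95% interval -2.12 to 0.444), and without WT 1 the median in OE against WT was -0.79 with 33 of 65 members lower on the same terms (camera adjusted p = 7.9e-22, adjusted p = 0.577 with an estimated correlation), which counts against WT 1 as the whole cause, but the list level then differed by -0.774 (95% interval -2.05 to 0.5), so the pools are too few to exclude it. A direct effect of pitx2c on sarcomere genes, for which the ratio of mybpc3 to tnnt2a, chosen after its values were seen (0.357 and 0.352 in OE, 0.945 and 0.942 in mutant, 0.812 and 0.899 in WT), makes a candidate, cannot be told apart from these on 2 pools a group.

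The second pattern is the lower level of skeletal muscle and neuron genes in mutant than in WT (medians -1.49 and -0.77), for which less attached tissue at dissection is a candidate cause. If every other tissue were scarcer, the 7 other cell type lists outside the heart would fall alike, but their level relative to the skeletal muscle and neuron lists was higher in mutant by 1.52 (95% interval 0.523 to 2.51), and over the 36 ways to choose 2 of 9 lists the adjusted p was 0.15. Liver and yolk were lower in 30 of 30 genes (level -0.744, 95% interval -2.36 to 0.871), which goes with less of every tissue, while erythrocytes were higher in 21 of 21 (1.25, interval -1.17 to 3.67), pigment cells in 18 of 21 (0.552, interval -0.0541 to 1.16) and the lens level by 0.872 (interval 0.368 to 1.38), which counts against it, but over the 9 lists lens and skeletal muscle both had an adjusted p of 0.0732, the 36 differences of 2 lists had a smallest adjusted p of 0.248, and no lens gene had a mean above 32.7, so this stays open. Less trunk tissue would lower hox genes of groups 4 and above more than those of groups 1 to 3, and their mean log2 differences were -1.94 over 9 genes and -0.765 over 10, a difference of -1.17 with exact permutation p = 0.059 over 92378 splits of genes, which are not independent. These explanations, and an effect of the mutation on these tissues, which was not tested, cannot be told apart here.

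The third pattern is that genes with large differences lay close together in mutant against WT, such as caspa, etv2 and zp3d.1 on chromosome 16, chosen here for their position (42043519 to 42116585). Of the 64 genes with an unadjusted p under 0.001 and a log2 difference of at least 2 in size, 9 pairs within 1 Mb shared no family name, against a mean of 3.39 in 1000 draws matched on expression, 6 of which gave as many. A difference in genetic background between the fish lines, with linked variants that alter expression or read mapping, would give such pairs and is a hypothesis, and it may also bear on bcan and dock11. Gene families side by side add 4 of 13 pairs, which leaves their part open. Family was read from the gene symbol, and clone-type names give none. Pairs with such a gene, as si:dkey-45k15.1 with exoc3l4, were among the 9, so families were not fully left out. Variants linked to pitx2 are argued against as the source of these pairs, which lay on other chromosomes. The count of 0 of the 64 genes within 5 Mb of pitx2 cannot decide this, since matched draws gave a mean of only 0.452. Pairs were counted in 3 ways, over unmatched draws (mean 3.35), matched draws (3.46) and without family pairs. In OE against WT there were 3 pairs (666 of 1000 draws as many) and in OE against mutant 14 (3 of 1000). The neighbours ahrrb and mcm6l on chromosome 2, chosen after their values were seen, were lower than WT in both other groups. Their log2 differences were -4.55 and -5.02 in mutant and -4.59 and -6.17 in OE.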
